A study of Mus musculus with 28 samples.

How the data were processed

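Messenger RNA of 28 mouse libraries was measured, 2 for each of 14 groups of fibroblasts, induced neural stem cells and neural stem cells, as the labels name them. Per the labels' protocols, total RNA was isolated with Trizol, messenger RNA was enriched with oligo(dT) beads and fragmented, and cDNA was made with random hexamers and sequenced on an Illumina instrument. The deposited table of the authors gave 1 score per gene and library, whole numbers described only as normalised expression values. RSEM, Bowtie2 2.0 and mm10 were named without order or role, per the submitters' processing notes, and how the values were normalised was not stated. The unit was left as score because the values were neither counts nor a known rate.

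The table held 17295 genes, and all of their identifiers were found in GENCODE M21 on GRCm38 (mm10), the source of the coordinates and chromosomes given. A symbol was shared with another gene for 18 genes. Every gene had a value of 21 or more in at least 2 libraries, so genes with lower values had been left out before deposition. Library totals spanned 0.051% of the lowest total. In each library exactly 10 genes stood at the same highest value, 92914, and 40 genes stood at it in at least 1 library. Such ties compress the fold changes of the most abundant genes. Genes at 0 made up 8.55 to 11.08% of a library. The largest ratio of library medians was 1.144 within a GC decile, 1.127 within as many random genes and 1.962 within a decile of transcript length. Sequencing depth cannot be recovered from such values, so the precision that depth gives is unknown. Replicates differed by a median of 0.075 to 0.207 in absolute log2 value in the fibroblast and miNSC groups and by 0.373 in the NSC group, whose libraries came from different passages. Of the tested genes, 6.26 to 12.06% had identical values in both replicates of a group.

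Values were changed to log2(value + 1) with no further normalisation. Genes with a mean of at least 10 over all libraries were tested, 16275 in number. A single linear model with 1 term per group was fitted with limma 3.58.1 (R 4.3.3), with a trend of the variance on the mean and no robust setting. The comparisons were contrasts of group means, each group weighing the same. P-values were adjusted over all tested genes by the method of Benjamini and Hochberg, with a threshold of 0.05. Interactions were tested as differences of differences in the same fit. Gene lists were written before the data were examined and tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, where at least 5 members were tested. Of 540 list results, fry passed 352 in its directional form and 467 in its mixed form. The directional form passed 167 of the 171 lists that camera passed. The preset correlation is lenient for co-regulated genes, and fry asks whether any shift exists rather than whether it exceeds that of other genes.

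The genes named were chosen by a rule fixed before the data were examined. Per comparison it took the 10 largest rises and 10 largest falls among genes past the threshold, with no overlap between the sides and a mean of at least 100 in a group compared. Overlap was not checked for interactions. Predicted and unnamed genes were left out, and genes at 0 on all of 1 side were given as listed at 0 rather than ranked. For each list described, the 4 members with the smallest adjusted p could be named too, and every member of the lists of reprogramming factors, Hox genes and sex-linked genes. The profile position was the projection of a library's log2 profile on the line from the fibroblast mean to the NSC mean.

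The main settings, a first set of alternatives and the rule for genes were chosen before the data were examined. Further alternatives were chosen after seeing the data, among them a robust variance prior and leaving out genes by GC content or chromosome. The mean of each group as 1 sample was chosen beforehand for miNSC against fibroblasts and afterwards for the counts of the 4 other comparisons. An alternative with a count tool, also chosen beforehand, was not run, because the values were not counts. The pipeline was tested on simulated data, in which 50 genes each were changed by 1.5, 2, 4 and 8-fold. It recovered 88, 96, 100 and 98% of them for miNSC against fibroblasts, 68, 90, 92 and 100% for adding B to KF, and 46, 76, 96 and 96% for adding M to KF. For the interaction of strain and B it recovered 18, 46, 82 and 94%, and 5.45 to 8.19% of calls were false over these comparisons. The simulated groups had equal spread and, beyond the changed genes, no differences between lines. These rates therefore do not cover differences between lines or groups of unequal spread. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the data and drew the figures, and statmod 1.5.0 served the blocked fits.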

Results

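Messenger RNA was sequenced from 28 mouse cell libraries in 14 groups of 2. In 10 groups the cells were induced neural stem cells (miNSC), made from fibroblasts with doxycycline-driven transcription factors and expanded from picked colonies. A cocktail is written with 1 letter per factor. F is eSox17FNV, an engineered variant of the transcription factor Sox17, and B, K and M are the letters given for the other factors. The cocktail named 4F holds B, K, M and F. Embryonic fibroblasts of ICR mice gave BKF and KF lines, and those of the Sox2-GFP reporter line gave BKF, KF and KMF lines. Tail-tip fibroblasts of 1.0-year Sox2-GFP mice gave BKF, KMF and 4F lines, the last sampled at passages 8 and 18. Ear fibroblasts of the same age gave a 4F line. Among miNSC, passages were given only for the tail-tip 4F line. The 3 fibroblast groups, all of Sox2-GFP mice, were tail-tip cells at 1.0 and 2.5 years and skin cells at 2.5 years. Neural stem cells (NSC) of 2.5-year Sox2-GFP mice were sampled at passages 2 and 5. Totals of the normalised values were nearly equal in every library, from 15563679 to 15571626. The sequencing depth of each library is therefore unknown, and no detection limit can be given.

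Levels are means ± SD over the libraries named. Log2 fold changes are given ± SE on the scale of log2(value + 1), which understates the change of genes with low values. Where several genes are named in a sentence, the values in parentheses are all log2 fold changes. Genes named with a fold change had no overlap between the libraries of the sides compared unless overlap is stated. For the interactions overlap was not checked. Replicates of 1 group may come from 1 picked colony, so the p-values measure only the spread between these libraries, part of which may be technical. Gene lists were tested with camera at a preset correlation between genes, and the median given for a list is its median log2 fold change. List calls printed without a second adjusted p also passed with an estimated correlation. Over the 20 comparisons, 171 list calls passed with the preset correlation and 72 with the estimated one.

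How far the induced cells had moved from fibroblast expression was asked with 20 miNSC and 6 fibroblast libraries. No embryonic, ear or ICR fibroblasts were sampled. The contrast therefore mixes reprogramming with differences of donor age, strain and tissue. Sox2, a regulator of neural stem cells, was listed at 0 in all fibroblast libraries and averaged 2003 ± 686 in miNSC. Olig1, a transcription factor of the oligodendrocyte lineage, and Gpm6a, a neuronal membrane glycoprotein, were also listed at 0 in fibroblasts, with 42162 ± 0 (a tied value in every library) and 11638 ± 1345 in miNSC. Mlc1 (ENSMUSG00000035805, chromosome 15, 88955884 to 88979007), a membrane protein of astrocytes, rose from 0.167 ± 0.408 to 4347 ± 742 (log2 fold change 11.90 ± 0.18, adjusted p = 1.27e-18). The potassium channel gene Kcnc1 (log2 fold change 11.67 ± 0.12), the chloride channel gene Ttyh1 (11.23 ± 0.22) and the brain proteoglycan gene Bcan (10.66 ± 0.17) rose as well. Type I collagen gene Col1a2 (ENSMUSG00000029661, chromosome 6, 4504814 to 4541544) fell from 42158 ± 0 to 3 ± 6.18 (log2 fold change -14.47 ± 0.77, adjusted p = 2.44e-11). The matrix proteoglycan gene Bgn (log2 fold change -13.95 ± 0.25) and the elastic fibre gene Efemp1 (-13.06 ± 0.82) fell too. In all, limma called 12450 of 16275 genes, 6966 higher and 5484 lower in miNSC, and 6468 of them changed at least 2-fold.

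Of 30 neural stem and progenitor genes, 28 rose and 1 fell (the same adjusted over the list alone). A median of 6.21 gave camera adjusted p = 2.25e-12. The neuronal microtubule gene Dcx was listed at 0 in fibroblasts and averaged 461 ± 200.4 in miNSC, and Map2, of the same function, rose (log2 fold change 7.59 ± 0.16). Among 13 neuron genes, 11 rose and 2 fell (the same adjusted over the list alone). A median of 4.88 gave camera adjusted p = 0.0064 and adjusted p = 0.0563 with an estimated correlation. The brain aldolase gene Aldoc rose (log2 fold change 10.05 ± 0.08), and the water channel gene Aqp4 was listed at 0 in fibroblasts against 666 ± 885 in miNSC. For 12 astrocyte genes, 8 rose and 3 fell (the same adjusted over the list alone). A median of 4.37 gave camera adjusted p = 0.0305 and adjusted p = 0.319 with an estimated correlation. The Notch ligand gene Dll1 rose (log2 fold change 9.84 ± 0.11). Within 16 Notch and Shh pathway genes, 13 rose and 1 fell (the same adjusted over the list alone). A median of 3.11 gave camera adjusted p = 4.46e-04 and adjusted p = 0.11 with an estimated correlation. Lists of forebrain, of midbrain and hindbrain and of oligodendrocyte genes did not pass in camera. Every listed fibroblast marker fell, such as the receptor gene Pdgfrb (log2 fold change -11.76 ± 0.13). Of 30 fibroblast genes, 0 rose and 30 fell (the same adjusted over the list alone). A median of -7.24 gave camera adjusted p = 2.25e-12. The actin-binding gene Tagln fell (log2 fold change -8.87 ± 0.13). Among 10 smooth muscle and myofibroblast genes, 0 rose and 10 fell (the same adjusted over the list alone). A median of -7.37 gave camera adjusted p = 1.81e-06. For 17 collagen and matrix turnover genes, 1 rose and 16 fell (the same adjusted over the list alone). A median of -5.35 gave camera adjusted p = 4.78e-07. The TGF beta binding protein gene Ltbp2 was listed at 0 in miNSC against 8355 ± 3787 in fibroblasts. Within 13 TGF beta and BMP targets, 3 rose and 10 fell (the same adjusted over the list alone). A median of -5.79 gave camera adjusted p = 0.00116.

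The antiviral membrane protein gene Bst2 (log2 fold change -8.61 ± 0.18) and B2m (-2.71 ± 0.07), the light chain of class I molecules, fell. Of 14 interferon genes, 1 rose and 13 fell (the same adjusted over the list alone). A median of -3.40 gave camera adjusted p = 8.32e-04. Among 10 antigen presentation genes, 0 rose and 9 fell (the same adjusted over the list alone). A median of -2.63 gave camera adjusted p = 2.22e-04. The insulin-like growth factor binding gene Igfbp7 fell (log2 fold change -9.30 ± 0.30). For 18 senescence and arrest genes, 4 rose and 14 fell (the same adjusted over the list alone). A median of -5.87 gave camera adjusted p = 0.00728 and adjusted p = 0.114 with an estimated correlation. Within 6 macrophage and leukocyte genes, 0 rose and 6 fell (the same adjusted over the list alone). A median of -6.30 gave camera adjusted p = 0.0067. Imprinted genes moved both ways, and their list of 15 tested members did not pass in camera. The imprinted RNA gene Meg3 was listed at 0 in all miNSC libraries against 2876 ± 767 in fibroblasts, and the adaptor gene Grb10 fell (log2 fold change -6.51 ± 0.10). The imprinted genes Mest (log2 fold change 9.42 ± 0.16) and Peg3 (5.16 ± 0.07) rose.

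Of the 7 listed reprogramming factor genes 6 had values here. Of 6 such genes, 5 rose and 1 fell (the same adjusted over the list alone). A median of 4.85 gave camera adjusted p = 0.0311 and adjusted p = 0.0702 with an estimated correlation. Besides Sox2, the POU factor gene Pou3f2 was listed at 0 in fibroblasts (786 ± 265 in miNSC), and Pou3f4 rose with overlap (log2 fold change 6.40 ± 0.20). Sox17, the gene from which the F factor derives, was at 76.2 ± 117 in miNSC and 0.167 ± 0.408 in fibroblasts (log2 fold change 3.31 ± 0.19, with overlap). The values do not separate transcripts of the chromosome from those of the lentiviral copies. Sox17 averaged 319 ± 91.9 in the tail-tip BKF line, 242 ± 28.3 in the ear 4F line and 140.5 ± 36.1 in the Sox2-GFP embryonic KF line. It was at 45.5 ± 23.3 in the tail-tip KMF line and at 9 or less in the others. With overlap, the zinc finger factor gene Klf4 fell (log2 fold change -2.17 ± 0.19) and the growth regulator gene Myc rose (0.52 ± 0.14). With the mean of each group as 1 sample, Sox17, Klf4 and Myc lost the call. Posterior Hox genes, which mark position along the body axis, all fell. Among 7 Hox genes of paralog groups 10 to 13, 0 rose and 7 fell (the same adjusted over the list alone). A median of -6.15 gave camera adjusted p = 2.22e-04. Hoxb3, of the anterior groups, rose (log2 fold change 3.15 ± 0.10). For 9 Hox genes of paralog groups 1 to 4, 8 rose and 1 fell (the same adjusted over the list alone). A median of 2.68 gave camera adjusted p = 0.0272 and adjusted p = 0.173 with an estimated correlation. The Y-linked gene Ddx3y was listed at 0 in both 2.5-year fibroblast groups and averaged 3996 ± 61.5 in the 1.0-year group, so the fibroblast groups differed in sex-linked expression. Within 5 sex-linked genes, 4 rose and 1 fell (the same adjusted over the list alone). A median of 4.29 gave camera adjusted p = 0.0493 and adjusted p = 0.164 with an estimated correlation. The rise of Ddx3y depended on the 2.5-year fibroblasts, since with 1.0-year fibroblasts only it turned to a log2 fold change of -0.856 (adjusted p = 1.68e-10). The list did not pass in tail-tip lines against 1.0-year tail-tip fibroblasts (camera adjusted p = 0.518).

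A profile position placed each library on the line from the fibroblast mean (0) to the NSC mean (1) over all tested genes. The miNSC group means lay between 0.81 (the ICR KF line) and 0.895 (the tail-tip KMF line), with a mean of 0.854 ± 0.031 (SD, n = 10 groups). Groups of embryonic origin averaged 0.846 ± 0.034 and groups of adult origin 0.861 ± 0.03 (SD, n = 5 each, with passages 8 and 18 of the tail-tip 4F line as 2 of the adult groups). The difference of -0.015 did not pass an exact two-sided permutation test (p = 0.437, 252 splits). With these passages averaged, chosen after seeing the data, 4 adult lines averaged 0.866 ± 0.023 (SD), and an exact permutation test against the 5 embryonic lines gave p = 0.325 over 126 splits. The position depended on the NSC library used, with a mean of 0.827 without the passage 2 library and 0.775 without the passage 5 library. Rank correlations across genes, which are not independent replicates, ranged from 0.906 to 0.938 between miNSC group means and NSC. Between miNSC and fibroblasts they ranged from 0.693 to 0.737.

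**Figure D1:**
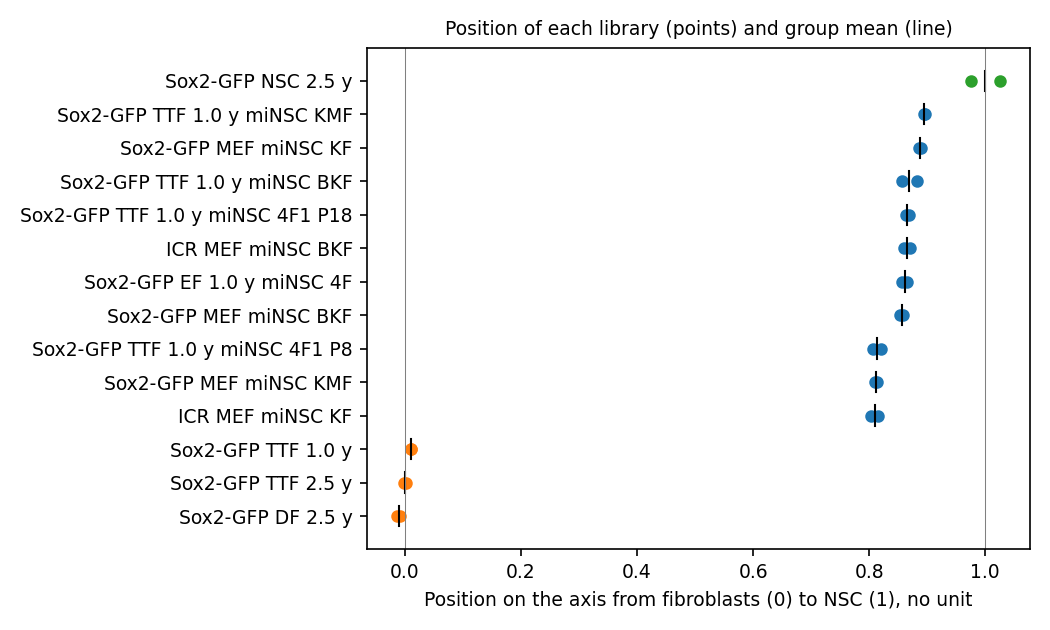
Profile position of each library (points) and group mean (lines) on the axis from the fibroblast mean at 0 to the NSC mean at 1, without unit, for the 14 groups of 2 libraries. The miNSC group means lie between 0.81 and 0.895, and the fibroblast group means between -0.011 and 0.01.

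Fibroblasts of the donor tissue and age were compared with the tail-tip lines made from them (8 miNSC libraries of BKF, KMF and 4F against 2 fibroblast libraries). Ttyh1, the chloride channel gene, rose from 1 ± 1.41 to 9424 ± 4853 (log2 fold change 12.19 ± 0.38, adjusted p = 4.70e-14), and Rtn1, a reticulon gene of neurons, rose too (11.32 ± 0.29). Gpm6a, the neuronal glycoprotein gene, was listed at 0 in these fibroblasts and averaged 12603 ± 846 in the lines. The galectin gene Lgals3 (log2 fold change -12.56 ± 0.41) and the collagen gene Col8a1 (-12.51 ± 1.14) fell. In these lines limma called 10748 genes, 5971 higher and 4777 lower, of which 6283 changed at least 2-fold. Of 30 neural stem and progenitor genes, 27 rose and 1 fell (28 and 1 adjusted over the list alone). A median of 6.51 gave camera adjusted p = 4.59e-14. Among 30 fibroblast genes, 0 rose and 29 fell (the same adjusted over the list alone). A median of -7.40 gave camera adjusted p = 1.80e-13.

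Each cocktail was also set against the same pair of tail-tip fibroblast libraries, with 2 libraries per side. In BKF cells the proteoglycan gene Cspg5 (log2 fold change 11.80 ± 0.32) and the myosin gene Myh14 (10.54 ± 0.31) rose. The pigment epithelium factor gene Serpinf1 (log2 fold change -12.28 ± 0.34) and the matricellular gene Thbs1 (-11.48 ± 0.71) fell. The limma count for BKF was 10041 genes (5593 higher, 4448 lower), and 6218 changed at least 2-fold. For 30 neural stem and progenitor genes, 27 rose and 1 fell (the same adjusted over the list alone). A median of 6.49 gave camera adjusted p = 9.77e-15. The glycolytic enzyme gene Gpi1 rose (log2 fold change 2.98 ± 0.26). Within 14 glycolysis genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone). A median of 1.97 gave camera adjusted p = 0.0298 and adjusted p = 0.483 with an estimated correlation.
In KMF cells Plekhb1, a gene of photoreceptors and brain, rose (log2 fold change 12.16 ± 0.27), and so did the cell adhesion gene Lrrn1 (10.60 ± 0.48). The collagen gene Col5a2 (log2 fold change -13.32 ± 1.34) and the guidance gene Slit3 (-12.12 ± 0.67) fell. KMF cells differed from the fibroblasts in 10242 genes (5549 higher, 4693 lower), and 6513 changed at least 2-fold. Lhx2, a cortical selector, rose (log2 fold change 6.83 ± 0.20). Of 9 forebrain genes, 6 rose and 1 fell (6 and 2 adjusted over the list alone). A median of 2.53 gave camera adjusted p = 0.0476 and adjusted p = 0.0995 with an estimated correlation.
In 4F cells at passage 8 the POU factor gene Pou3f3 (log2 fold change 10.32 ± 0.73) and the potassium channel gene Kcnd3 (10.39 ± 0.42) rose. The collagen-crosslinking gene Lox (log2 fold change -12.07 ± 0.98) and the microfibril gene Mfap5 (-11.55 ± 1.06) fell. The 4F count was 9845 genes (5588 higher, 4257 lower), with 6071 at least 2-fold. Among 30 neural stem and progenitor genes, 27 rose and 0 fell (the same adjusted over the list alone). A median of 7.72 gave camera adjusted p = 5.31e-16. For 10 antigen presentation genes, 0 rose and 10 fell (the same adjusted over the list alone). A median of -2.87 gave camera adjusted p = 5.95e-05. These comparisons share their control libraries, so no overlap between their calls was counted.

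What still set the induced cells apart from NSC was asked with 20 miNSC and 2 NSC libraries, the latter at passages 2 and 5. The astrocyte enzyme gene Aldh1l1 (log2 fold change -7.70 ± 0.18, adjusted p = 1.31e-14) and the cell cycle kinase gene Cdk6 (-6.42 ± 0.34) were lower in miNSC. The antiviral membrane protein gene Ifitm3 (log2 fold change 6.52 ± 0.27), the astrocyte-secreted matrix gene Sparcl1 (6.48 ± 0.23) and the T-box gene Tbx15 (5.53 ± 0.15) were higher. So was Klf4, at 639 ± 956 in miNSC and 5 ± 1.41 in NSC (log2 fold change 5.79 ± 0.30). From this contrast limma called 6610 genes, 3407 higher and 3203 lower in miNSC, and 2158 changed at least 2-fold. The 2 NSC libraries were over 2-fold apart in 3141 tested genes, against 787 to 1201 in the other groups. The variance shared over all groups is therefore likely too small for NSC.

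Regional genes separated miNSC from NSC. The eye-field gene Six3 was lower (log2 fold change -5.71 ± 0.21). Within 9 forebrain genes, 1 was higher and 5 lower (2 and 5 adjusted over the list alone). A median of -0.87 gave camera adjusted p = 0.00327. The homeobox genes En1 (log2 fold change 2.56 ± 0.22) and, with overlap, En2 (3.60 ± 0.33) were higher. Of 8 midbrain and hindbrain genes, 7 were higher and 0 were lower (the same adjusted over the list alone). A median of 1.58 gave camera adjusted p = 7.65e-04. Hoxb2 and Hoxb3 were listed at 0 in NSC and averaged 207 ± 125 and 545 ± 403 in miNSC. Among 9 Hox genes of paralog groups 1 to 4, 9 were higher and 0 were lower (the same adjusted over the list alone). A median of 3.39 gave camera adjusted p = 4.47e-08. Hoxb8 was listed at 0 in NSC against 849.6 ± 1033 in miNSC. For 14 Hox genes of paralog groups 5 to 9, 10 were higher and 0 were lower (the same adjusted over the list alone). A median of 3.67 gave camera adjusted p = 3.45e-08. The nuclear receptor gene Nr2e1 (log2 fold change -4.84 ± 0.20) and the SOX factor gene Sox1 (-5.48 ± 0.31) were lower. Within 30 neural stem and progenitor genes, 5 were higher and 14 lower (5 and 15 adjusted over the list alone). A median of -0.34 gave camera adjusted p = 4.02e-04. The tubulin gene Tubb3 was lower (log2 fold change -2.47 ± 0.19). Of 13 neuron genes, 0 were higher and 8 were lower (0 and 9 adjusted over the list alone). A median of -1.32 gave camera adjusted p = 4.88e-04. The astrocyte filament gene Gfap was at 1269.8 ± 2502 in miNSC and 10614 ± 390.3 in NSC (log2 fold change -5.46 ± 0.33). Among 12 astrocyte genes, 3 were higher and 8 lower (3 and 9 adjusted over the list alone). A median of -1.76 gave camera adjusted p = 9.93e-04 and adjusted p = 0.238 with an estimated correlation. The proteoglycan gene Cspg4 was lower with overlap (log2 fold change -4.21 ± 0.31). For 8 oligodendrocyte genes, 1 was higher and 4 lower (the same adjusted over the list alone). A median of -0.65 gave camera adjusted p = 0.0242 and adjusted p = 0.268 with an estimated correlation.

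Most glycolysis and proliferation genes were higher in miNSC than in NSC. The lactate dehydrogenase gene Ldha (log2 fold change 2.75 ± 0.27) was an example, and so, with overlap, was the replication factor gene Pcna (1.34 ± 0.39). Without the passage 2 library, the log2 fold change of Pcna fell to 0.125 and the call was lost. Within 14 glycolysis genes, 13 were higher and 0 were lower (the same adjusted over the list alone). A median of 1.86 gave camera adjusted p = 2.08e-06 and adjusted p = 0.263 with an estimated correlation. Of 20 proliferation genes, 14 were higher and 0 were lower (20 and 0 adjusted over the list alone). A median of 1.52 gave camera adjusted p = 7.65e-04 and adjusted p = 0.54 with an estimated correlation. The inhibitor of differentiation gene Id1 was higher too (log2 fold change 2.02 ± 0.29). Among 13 TGF beta and BMP targets, 7 were higher and 1 lower (the same adjusted over the list alone). A median of 1.38 gave camera adjusted p = 0.0307 and adjusted p = 0.0893 with an estimated correlation. The X-inactivation gene Xist was at 67536 ± 35889.9 in NSC and 195 ± 31.5 in miNSC, and Ddx3y was listed at 0 in NSC. For 5 sex-linked genes, 4 were higher and 1 lower (the same adjusted over the list alone). A median of 10.66 gave camera adjusted p = 2.58e-04. Sex and cell type cannot be separated for these genes.

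The NSC libraries gave the size of the gap that reprogramming had to cross (2 NSC against 6 fibroblast libraries). Gfap, the astrocyte filament gene, was at 0.167 ± 0.408 in fibroblasts and 10614 ± 390.3 in NSC (log2 fold change 13.21 ± 0.36). The brain receptor gene Gpr37l1 (log2 fold change 12.91 ± 0.20) and the Wnt ligand gene Wnt7b (12.50 ± 0.23) were higher in NSC. The collagen gene Col3a1 (log2 fold change -12.63 ± 0.77) and the TGF beta docking gene Lrrc32 (-12.67 ± 0.38) were lower. Between these cell types limma called 10728 genes, 5674 higher and 5054 lower, 6371 of them at least 2-fold. Here too the shared variance is likely too small for NSC. Within 30 neural stem and progenitor genes, 29 were higher and 1 lower (the same adjusted over the list alone). A median of 8.31 gave camera adjusted p = 2.70e-16. Hoxb9 was listed at 0 in NSC and averaged 705 ± 397 in fibroblasts. Of 14 Hox genes of paralog groups 5 to 9, 1 was higher and 13 lower (the same adjusted over the list alone). A median of -5.12 gave camera adjusted p = 6.33e-06.

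Whether the donor age and tissue left a mark was asked with Sox2-GFP lines of BKF and KMF, with 4 embryonic and 4 tail-tip libraries. The Hox gene Hoxb6 (ENSMUSG00000000690, chromosome 11, 96292476 to 96301569) was lower in embryonic lines (log2 fold change -6.64 ± 0.28, adjusted p = 9.81e-11), as were Hoxb9 (-6.41 ± 0.25) and Hoxb8 (-5.53 ± 0.18). The ventral neural tube gene Nkx6-1 (log2 fold change -6.44 ± 0.24) and the glial potassium channel gene Kcnj10 (-5.93 ± 0.46) were also lower. The tubulin gene Tuba1c (log2 fold change 6.93 ± 0.55), the peptide hormone gene Calca (6.79 ± 0.43) and the fibronectin domain gene Fndc1 (5.53 ± 0.29) were higher in embryonic lines. For donor, limma called 5377 genes, 2807 higher and 2570 lower in embryonic lines, and 1248 changed at least 2-fold. Among 14 Hox genes of paralog groups 5 to 9, 3 were higher and 6 lower (the same adjusted over the list alone). A median of -0.87 gave camera adjusted p = 0.0208 and adjusted p = 0.303 with an estimated correlation. Sox2 (log2 fold change -1.27 ± 0.08) and the SOX factor gene Sox9 (-1.08 ± 0.08) were lower. For 30 neural stem and progenitor genes, 3 were higher and 13 lower (4 and 13 adjusted over the list alone). A median of -0.34 gave camera adjusted p = 0.0238 and adjusted p = 0.303 with an estimated correlation. The kinase gene Pdk1 was lower (log2 fold change -1.91 ± 0.38). Within 14 glycolysis genes, 0 were higher and 10 were lower (the same adjusted over the list alone). A median of -0.93 gave camera adjusted p = 0.00667 and adjusted p = 0.625 with an estimated correlation. The Y-linked gene Eif2s3y was lower (log2 fold change -2.35 ± 0.07). Of 5 sex-linked genes, 0 were higher and 2 were lower (the same adjusted over the list alone). A median of -0.28 gave camera adjusted p = 0.0379 and adjusted p = 0.333 with an estimated correlation. With the mean of each line as 1 sample, 2 lines against 2, limma called 62 genes, and 10 of the 12 genes named here lost the call.

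**Figure D2:**
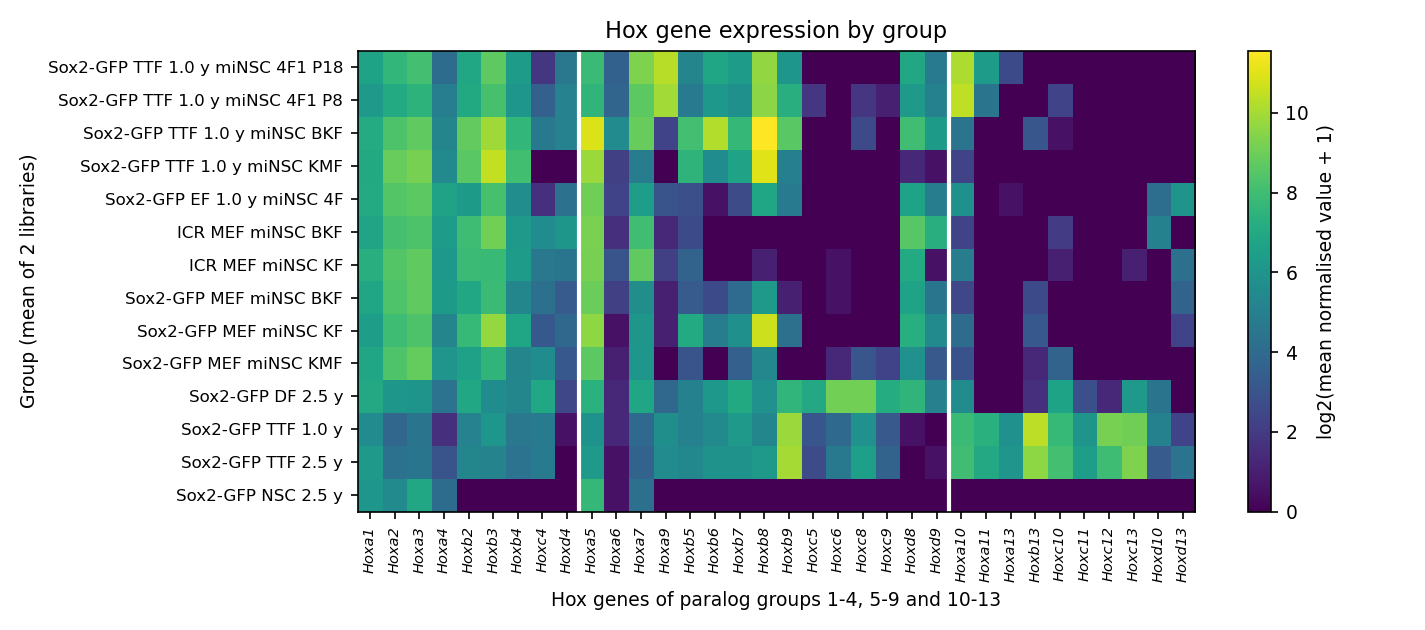
Hox genes of paralog groups 1 to 4, 5 to 9 and 10 to 13 (left to right) in the 14 groups, as log2(mean value + 1) of the 2 libraries of each group. Hoxb8 averages 3019 in the tail-tip BKF line, 72 in the Sox2-GFP embryonic BKF line and 0 in NSC.

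The cocktails BKF and KMF were compared over both donors, with 4 libraries each. The chondroitin sulphate proteoglycan gene Cspg4 (log2 fold change 4.07 ± 0.30), the stress response gene Ier3 (5.14 ± 0.37) and the lactate transporter gene Slc16a3 (4.76 ± 0.64) were higher with BKF. The collagen chaperone gene Fkbp10 (log2 fold change -2.83 ± 0.24) and the water channel gene Aqp4 (-1.85 ± 0.17) were lower. Here limma called 1767 genes, 864 higher and 903 lower with BKF, and 417 changed at least 2-fold. Hoxd8 (log2 fold change 3.77 ± 0.20) and Hoxd9 (3.52 ± 0.27) were higher. Among 14 Hox genes of paralog groups 5 to 9, 6 were higher and 1 lower (10 and 1 adjusted over the list alone). A median of 0.75 gave camera adjusted p = 3.30e-05. The mean log2 value of this list was 6.02 with BKF and 3.73 with KMF in tail-tip lines. In embryonic lines it was 3.14 and 3.02, so the difference lay mainly between the tail-tip lines. The glucose transporter gene Slc2a1 was higher with overlap (log2 fold change 0.86 ± 0.18). For 14 glycolysis genes, 6 were higher and 0 were lower (11 and 1 adjusted over the list alone). A median of 0.82 gave camera adjusted p = 8.16e-05 and adjusted p = 0.498 with an estimated correlation. Within 12 astrocyte genes, 1 was higher and 4 lower (1 and 5 adjusted over the list alone). A median of -0.24 gave camera adjusted p = 0.0438 and adjusted p = 0.498 with an estimated correlation. Of 14 oxidative phosphorylation genes, 1 was higher and 0 were lower (3 and 0 adjusted over the list alone). A median of 0.21 gave camera adjusted p = 0.0135 and adjusted p = 0.544 with an estimated correlation. With the mean of each line as 1 sample, limma called 38 genes for the cocktails, and 8 of the 8 genes named here lost the call. Leaving out 1 library moved the count to 1143 (embryonic BKF replicate 1), 1153 (embryonic KMF replicate 2), 1145 (tail-tip KMF replicate 1) or 1173 (tail-tip KMF replicate 2), and leaving out the NSC libraries to 3012 (2992 with the replicate block).

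Whether the difference between BKF and KMF depended on the donor was tested as an interaction, the BKF minus KMF difference in embryonic lines minus that in tail-tip lines. Matn4, a matrilin gene, had 85.5 ± 16.3 with BKF and 6.5 ± 2.12 with KMF in embryonic lines. In tail-tip lines it had 1.5 ± 0.707 and 286 ± 29.7 (interaction 10.41 ± 0.54 on the log2 scale, adjusted p = 4.93e-09). The kinase gene Brsk2 (6.04 ± 0.61) and the retinal determination gene Dach1 (5.49 ± 1.38) had positive interactions, the latter lost without tail-tip KMF replicate 2. The potassium channel gene Kcnt2 (-8.21 ± 0.29) and the matrix gene Aebp1 (-7.09 ± 0.83) had negative ones. As interactions limma called 2132 genes, 1030 positive and 1102 negative, of which 1097 were at least 2-fold. Hoxd8 had a negative interaction (-5.86 ± 0.41). Among 14 interactions of Hox genes of paralog groups 5 to 9, 0 were positive and 7 were negative (the same adjusted over the list alone). A median of -1.75 gave camera adjusted p = 3.34e-05 and adjusted p = 0.0512 with an estimated correlation. The complex III gene Uqcrc1 had one of -0.88 ± 0.15. For 14 interactions of oxidative phosphorylation genes, 0 were positive and 9 were negative (0 and 12 adjusted over the list alone). A median of -0.87 gave camera adjusted p = 2.04e-07 and adjusted p = 0.372 with an estimated correlation. The count fell to 1390 without embryonic BKF replicate 2, 1383 without embryonic KMF replicate 2, 1374 without tail-tip BKF replicate 2 and 1355 without tail-tip KMF replicate 2, and was 3519 without the NSC libraries (3531 with the replicate block).

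What B added to KF was asked in embryonic lines of both strains, with 4 BKF and 4 KF libraries. Klf4, the zinc finger factor gene, was at 182 ± 180.2 with BKF and 2034 ± 1557 with KF (adjusted p = 8.72e-08). The annexin gene Anxa5 (log2 fold change -4.01 ± 0.10) and the collagen gene Col6a1 (-4.63 ± 0.68) were lower with B. The potassium channel gene Kcnt2 (log2 fold change 7.89 ± 0.15), the neural crest gene Pax3 (6.27 ± 0.55) and Cspg4 (5.43 ± 0.30) were higher. With B limma called 4177 genes, 2129 higher and 2048 lower, and 957 changed at least 2-fold. Sparcl1 (log2 fold change -3.21 ± 0.22) and, with overlap, Aldh1l1 (-1.68 ± 0.17) were lower. Within 12 astrocyte genes, 0 were higher and 10 were lower (the same adjusted over the list alone). A median of -1.16 gave camera adjusted p = 4.72e-07 and adjusted p = 0.0707 with an estimated correlation. Of 30 fibroblast genes, 1 was higher and 14 lower (1 and 16 adjusted over the list alone). A median of -0.95 gave camera adjusted p = 1.89e-04. The cyclin gene Ccne1 was higher with overlap (log2 fold change 1.32 ± 0.21). Among 20 proliferation genes, 3 were higher and 0 were lower (2 and 0 adjusted over the list alone). A median of 1.26 gave camera adjusted p = 2.46e-04 and adjusted p = 0.721 with an estimated correlation. The interactions with strain, given below, had medians of the opposite sign for the astrocyte and proliferation lists. By the medians these shifts therefore lay mostly in Sox2-GFP lines and were small in ICR lines. The Sox2-GFP side held 1 KF line, the miNSC group lowest in Mki67 and near NSC in Gfap, as given at the end. Id2, an inhibitor of differentiation, was lower with overlap (log2 fold change -1.73 ± 0.14). For 13 TGF beta and BMP targets, 1 was higher and 4 lower (1 and 7 adjusted over the list alone). A median of -0.73 gave camera adjusted p = 0.0179 and adjusted p = 0.0707 with an estimated correlation. Within 5 sex-linked genes, 0 were higher and 3 were lower (the same adjusted over the list alone). A median of -0.43 gave camera adjusted p = 0.00115 and adjusted p = 0.0707 with an estimated correlation. With the mean of each line as 1 sample, limma called 37 genes for B, and 9 of the 10 genes named here lost the call.

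The effect of B was tested for a difference between strains, as BKF minus KF in ICR minus the same in Sox2-GFP lines. Egr4, an immediate early zinc finger gene, was at 265 ± 1.41 with BKF and 2.5 ± 0.707 with KF in ICR. In Sox2-GFP lines it was at 70 ± 0 and 6924 ± 89.8 (interaction 12.87 ± 0.79, adjusted p = 7.67e-09). Calca, the peptide hormone gene, was at 1 ± 1.41 and 2432 ± 238 in ICR against 1070 ± 139 and 2 ± 1.41 in Sox2-GFP lines (interaction -19.01 ± 0.87). For this interaction limma called 5229 genes, 2565 positive and 2664 negative, and it was at least 2-fold in 3005. Gfap (6.64 ± 0.62) and Aqp4 (3.45 ± 0.34) had positive interactions. Of 12 interactions of astrocyte genes, 9 were positive and 0 were negative (10 and 0 adjusted over the list alone). A median of 2.10 gave camera adjusted p = 7.10e-05 and adjusted p = 0.24 with an estimated correlation. The myosin light chain gene Myl9 had one of 9.15 ± 0.84. Among 10 interactions of smooth muscle and myofibroblast genes, 7 were positive and 1 negative (the same adjusted over the list alone). A median of 2.11 gave camera adjusted p = 0.012 and adjusted p = 0.307 with an estimated correlation. Hoxd9 had one of 7.76 ± 0.53. For 14 interactions of Hox genes of paralog groups 5 to 9, 7 were positive and 0 were negative (the same adjusted over the list alone). A median of 1.24 gave camera adjusted p = 0.00625 and adjusted p = 0.24 with an estimated correlation. Within 20 interactions of proliferation genes, 0 were positive and 4 were negative (the same adjusted over the list alone). A median of -2.27 gave camera adjusted p = 0.00625 and adjusted p = 0.658 with an estimated correlation.

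Embryonic lines of the strains were compared over BKF and KF, with 4 libraries each. Hoxb8 (log2 fold change -7.94 ± 0.18), the cadherin gene Cdh20 (-8.45 ± 0.38) and the actin-binding gene Tagln2 (-8.57 ± 0.40) were lower in ICR lines. The imprinted gene Nnat averaged 1 ± 0 and 4 ± 1.41 in the ICR BKF and KF lines against 1973 ± 63.6 and 4775 ± 91.9 in those of Sox2-GFP. The lymphotoxin receptor gene Ltbr (log2 fold change 7.04 ± 0.28), the antiviral gene Trim5 (5.92 ± 0.84) and the lipid transporter gene Mfsd2a (4.86 ± 0.28) were higher. Between strains limma called 6242 genes, 3135 higher and 3107 lower in ICR, and 1648 changed at least 2-fold. The signal transducer gene Stat2 was higher (log2 fold change 1.57 ± 0.22). Of 14 interferon genes, 9 were higher and 1 lower (12 and 1 adjusted over the list alone). A median of 2.07 gave camera adjusted p = 0.00367 and adjusted p = 0.268 with an estimated correlation. The myelin enzyme gene Cnp was lower (log2 fold change -1.30 ± 0.13). Among 8 oligodendrocyte genes, 0 were higher and 6 were lower (the same adjusted over the list alone). A median of -1.55 gave camera adjusted p = 0.00367 and adjusted p = 0.268 with an estimated correlation. For 20 proliferation genes, 9 were higher and 0 were lower (the same adjusted over the list alone). A median of 1.31 gave camera adjusted p = 0.00367 and adjusted p = 0.845 with an estimated correlation. The enolase gene Eno1 was lower (log2 fold change -1.45 ± 0.27). Within 14 glycolysis genes, 0 were higher and 7 were lower (0 and 8 adjusted over the list alone). A median of -0.64 gave camera adjusted p = 0.0411 and adjusted p = 0.845 with an estimated correlation. With the mean of each line as 1 sample, limma called 69 genes for strain, and 9 of the 10 genes named here lost the call.

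What M added to KF was asked in 1 line each of Sox2-GFP embryonic origin, with 2 libraries per line, so line and cocktail cannot be separated. The same 2 KF libraries also entered adding B to KF, its interaction with strain and the comparison of strains. These results are therefore not independent. Gfap, the astrocyte filament gene, was at 168 ± 3.54 with KMF and 8316 ± 142 with KF (log2 fold change -5.62 ± 0.44), and Klf4 was at 462 ± 31.8 and 3382 ± 22.6 (-2.87 ± 0.41). The replication gene Mcm2 (log2 fold change 2.49 ± 0.56), the cell cycle activator gene E2f1 (3.61 ± 0.86) and the matrix enzyme enhancer gene Pcolce (6.38 ± 0.30) were higher with M. The lactate transporter gene Slc16a3 (log2 fold change -7.75 ± 0.91) and the neurotensin receptor gene Ntsr2 (-7.25 ± 0.42) were lower. On adding M limma called 6358 genes, 3235 higher and 3123 lower, and 2765 changed at least 2-fold. Of 20 proliferation genes, 13 were higher and 0 were lower (16 and 0 adjusted over the list alone). A median of 2.10 gave camera adjusted p = 5.18e-04 and adjusted p = 0.722 with an estimated correlation. Among 12 astrocyte genes, 1 was higher and 10 lower (the same adjusted over the list alone). A median of -1.10 gave camera adjusted p = 5.18e-04 and adjusted p = 0.303 with an estimated correlation. For 14 Hox genes of paralog groups 5 to 9, 3 were higher and 7 lower (3 and 8 adjusted over the list alone). A median of -1.22 gave camera adjusted p = 0.0115 and adjusted p = 0.228 with an estimated correlation. Sox17 (log2 fold change -4.38 ± 0.41) and Sox2 (-1.21 ± 0.11) were lower. Within 6 reprogramming factor genes, 0 were higher and 3 were lower (0 and 4 adjusted over the list alone). A median of -0.99 gave camera adjusted p = 0.0115 and adjusted p = 0.153 with an estimated correlation. Of 18 senescence and arrest genes, 7 were higher and 0 were lower (the same adjusted over the list alone). A median of 0.69 gave camera adjusted p = 0.0407 and adjusted p = 0.303 with an estimated correlation.

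In tail-tip lines, 4F at passage 8 was compared with BKF for the addition of M (2 libraries of 1 line each). No passage was given for the BKF line, so line, passage and cocktail cannot be separated. Hoxa9 (log2 fold change 7.58 ± 0.69, adjusted p = 1.09e-06), Hoxa10 (6.02 ± 1.09) and the growth factor gene Ctgf (7.42 ± 0.68) were higher with 4F. The potassium channel gene Kcnt2 (log2 fold change -8.30 ± 0.21), the homeobox gene Barx1 (-6.63 ± 0.42) and the glial adhesion gene Hepacam (-4.81 ± 0.25) were lower. Against BKF limma called 4240 genes, 2136 higher and 2104 lower with 4F, and 1470 changed at least 2-fold. The isomerase gene Tpi1 was lower (log2 fold change -2.58 ± 0.33). Among 14 glycolysis genes, 0 were higher and 12 were lower (the same adjusted over the list alone). A median of -1.93 gave camera adjusted p = 2.68e-06 and adjusted p = 0.258 with an estimated correlation. The imprinted genes Ndn (log2 fold change 2.82 ± 0.22) and Peg10 (1.36 ± 0.16) were higher. For 15 imprinted genes, 8 were higher and 0 were lower (the same adjusted over the list alone). A median of 0.84 gave camera adjusted p = 1.62e-04. Within 12 astrocyte genes, 0 were higher and 8 were lower (0 and 9 adjusted over the list alone). A median of -0.87 gave camera adjusted p = 1.62e-04 and adjusted p = 0.155 with an estimated correlation. Of 10 antigen presentation genes, 0 were higher and 5 were lower (0 and 6 adjusted over the list alone). A median of -1.06 gave camera adjusted p = 0.00237 and adjusted p = 0.0893 with an estimated correlation. Among 14 Hox genes of paralog groups 5 to 9, 2 were higher and 8 lower (the same adjusted over the list alone). A median of -1.27 gave camera adjusted p = 0.0177 and adjusted p = 0.155 with an estimated correlation. With only the groups compared in the fit limma called 561 genes, and 5 of the 9 genes named here lost the call. Without 4F replicate 1 it called 2726.

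Against KMF, the same 4F libraries gave the addition of B (2 libraries of 1 line each). The KMF line had no passage given either, so line, passage and cocktail cannot be separated. The fibronectin domain gene Fndc1 (log2 fold change 9.96 ± 0.41, adjusted p = 5.82e-11), Hoxa10 (8.10 ± 1.09) and the cilium gene Evc2 (8.73 ± 0.28) were higher with 4F. The glial adhesion gene Hepacam (log2 fold change -5.08 ± 0.25) and the retinal homeobox gene Vax2 (-5.18 ± 0.47) were lower. Against KMF limma called 5781 genes, 2943 higher and 2838 lower with 4F, and 2287 changed at least 2-fold. For 14 glycolysis genes, 1 was higher and 11 lower (1 and 12 adjusted over the list alone). A median of -1.47 gave camera adjusted p = 7.79e-04 and adjusted p = 0.455 with an estimated correlation. Cycs, the gene of cytochrome c, was higher (log2 fold change 1.76 ± 0.28). Within 14 oxidative phosphorylation genes, 11 were higher and 0 were lower (the same adjusted over the list alone). A median of 0.59 gave camera adjusted p = 7.79e-04 and adjusted p = 0.455 with an estimated correlation. Of 12 astrocyte genes, 0 were higher and 7 were lower (0 and 9 adjusted over the list alone). A median of -1.17 gave camera adjusted p = 7.79e-04 and adjusted p = 0.251 with an estimated correlation. The forebrain gene Otx1 was lower (log2 fold change -3.74 ± 0.31). Among 9 forebrain genes, 1 was higher and 6 lower (the same adjusted over the list alone). A median of -1.77 gave camera adjusted p = 0.0437 and adjusted p = 0.21 with an estimated correlation.

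The tail-tip 4F line was followed in culture from passage 8 to passage 18 (2 libraries each). Gfap, the astrocyte filament gene, rose from 16 ± 5.66 to 1588 ± 1357 (log2 fold change 6.26 ± 0.44, adjusted p = 6.87e-08), and Aqp4, the water channel gene, from 84 ± 8.48 to 2921 ± 1418 (5.02 ± 0.24). The thioredoxin inhibitor gene Txnip rose too (log2 fold change 5.16 ± 0.43). The growth factor gene Ctgf (log2 fold change -6.62 ± 0.68), the synaptic gene Arc (-6.47 ± 0.75) and the growth arrest gene Gas6 (-4.76 ± 0.77) fell. Over these passages limma called 5716 genes, 2848 higher and 2868 lower at passage 18, and 2154 changed at least 2-fold. For 12 astrocyte genes, 9 rose and 1 fell (the same adjusted over the list alone). A median of 1.83 gave camera adjusted p = 1.59e-04 and adjusted p = 0.402 with an estimated correlation. Gpr17, a receptor gene of oligodendrocyte precursors, rose (log2 fold change 4.91 ± 0.71). Within 8 oligodendrocyte genes, 5 rose and 0 fell (the same adjusted over the list alone). A median of 1.42 gave camera adjusted p = 0.0162 and adjusted p = 0.402 with an estimated correlation. The replication genes Mcm4 (log2 fold change -2.29 ± 0.41) and Mcm2 (-2.64 ± 0.56) fell. Of 20 proliferation genes, 0 rose and 10 fell (the same adjusted over the list alone). A median of -1.80 gave camera adjusted p = 3.86e-04 and adjusted p = 0.741 with an estimated correlation. With only the groups compared in the fit the count was 2169 genes, and 5 of the 9 genes named here lost the call. These were Gfap (limma adjusted p = 0.0509), Gpr17, Mcm2, Arc and Ctgf.

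Donor sites of adult 4F lines were compared as ear against tail-tip at passage 8 (2 libraries of 1 line each). No passage was given for the ear line, so line, passage and donor site cannot be separated. The same tail-tip 4F libraries also entered the comparisons with BKF and KMF above, so these results are not independent. Against tail-tip BKF these 4F libraries had 0 glycolysis genes higher and 12 lower, and 8 imprinted genes higher and 0 lower. Both lists thus also differed between lines of 1 donor site. Hox genes of paralog groups 5 to 9 (2 higher, 8 lower) did not mirror the ear result. The cerebellar zinc finger gene Zic1 (log2 fold change 8.49 ± 0.46, adjusted p = 1.91e-09), the GABA transporter gene Slc6a11 (5.46 ± 0.29) and the neural crest gene Tfap2a (4.66 ± 0.44) were higher in the ear line. Hoxa9 (log2 fold change -6.89 ± 0.69), Calca (-7.67 ± 0.61) and the guidance receptor gene Dcc (-6.84 ± 1.21) were lower. Between these lines limma called 4419 genes, 2169 higher and 2250 lower in the ear line, and 1681 changed at least 2-fold. The collagen gene Col12a1 was lower (log2 fold change -3.01 ± 0.26). Among 17 collagen and matrix turnover genes, 1 was higher and 14 lower (the same adjusted over the list alone). A median of -1.92 gave camera adjusted p = 8.18e-07. For 14 Hox genes of paralog groups 5 to 9, 1 was higher and 7 lower (the same adjusted over the list alone). A median of -1.85 gave camera adjusted p = 9.18e-05. Within 9 forebrain genes, 6 were higher and 0 were lower (the same adjusted over the list alone). A median of 1.54 gave camera adjusted p = 0.00157. Of 14 glycolysis genes, 12 were higher and 0 were lower (the same adjusted over the list alone). A median of 1.83 gave camera adjusted p = 8.18e-07 and adjusted p = 0.253 with an estimated correlation. Among 15 imprinted genes, 0 were higher and 6 were lower (0 and 7 adjusted over the list alone). A median of -0.83 gave camera adjusted p = 6.52e-04. With only the groups compared in the fit Dcc lost the call (adjusted p = 0.146). The count was 2824 without ear replicate 1 and 2935 without tail-tip 4F replicate 1.

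Age was compared in the starting tail-tip fibroblasts, with 2 libraries per age. The lysosomal macrophage gene Cd68 (log2 fold change 3.73 ± 0.41, adjusted p = 2.42e-05), the macrophage receptor gene Adgre1 (2.85 ± 0.59) and the matrix protease gene Mmp9 (4.19 ± 0.57) were higher at 2.5 years. The Wnt ligand gene Wnt4 (log2 fold change -3.90 ± 0.45), the nuclear receptor gene Nr4a3 (-3.93 ± 0.47) and the nuclear RNA gene Malat1 (-3.98 ± 0.15) were lower. Xist was listed at 0 at 1.0 year and was at 21805 ± 0 at 2.5 years, and Ddx3y and Eif2s3y were listed at 0 at 2.5 years. Age and sex cannot therefore be separated. Between ages limma called 1797 genes, 916 higher and 881 lower at 2.5 years, and 525 changed at least 2-fold. For 6 macrophage and leukocyte genes, 3 were higher and 0 were lower (the same adjusted over the list alone). A median of 2.82 gave camera adjusted p = 0.00198. Within 5 sex-linked genes, 1 was higher and 3 lower (1 and 4 adjusted over the list alone). A median of -6.37 gave camera adjusted p = 2.70e-07. Of 14 interferon genes, 2 were higher and 0 were lower (3 and 0 adjusted over the list alone). A median of 1.24 gave camera adjusted p = 0.0396 and adjusted p = 0.242 with an estimated correlation. The count was 949 without 1.0-year replicate 1, 915 without 1.0-year replicate 2 and 852 without 2.5-year replicate 2, against 2964 without the NSC libraries (2978 with the replicate block).

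Skin and tail-tip fibroblasts of 2.5-year mice were compared as donor sites (2 libraries each). The leukotriene enzyme gene Ltc4s (log2 fold change 10.43 ± 0.36, adjusted p = 2.38e-12), the progesterone receptor gene Pgr (7.89 ± 0.91) and the zinc finger factor gene Gata6 (7.88 ± 0.56) were higher in skin. The thrombospondin gene Thbs4 (log2 fold change -13.13 ± 0.45), the cartilage matrix gene Cilp (-6.72 ± 0.80), Hoxb13 (-8.07 ± 0.54) and Hoxc12 (-6.66 ± 0.27) were lower. Between tissues limma called 4322 genes, 1956 higher and 2366 lower in skin, and 1856 changed at least 2-fold. Among 7 Hox genes of paralog groups 10 to 13, 0 were higher and 6 were lower (0 and 7 adjusted over the list alone). A median of -3.69 gave camera adjusted p = 3.50e-07. For 14 Hox genes of paralog groups 5 to 9, 9 were higher and 1 lower (9 and 2 adjusted over the list alone). A median of 1.90 gave camera adjusted p = 0.00202 and adjusted p = 0.0748 with an estimated correlation. Within 9 Hox genes of paralog groups 1 to 4, 6 were higher and 0 were lower (7 and 0 adjusted over the list alone). A median of 1.48 gave camera adjusted p = 0.00346 and adjusted p = 0.171 with an estimated correlation. Of 9 forebrain genes, 5 were higher and 1 lower (the same adjusted over the list alone). A median of 1.00 gave camera adjusted p = 0.00796 and adjusted p = 0.0616 with an estimated correlation.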

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

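The tests of Hox position, of leftover fibroblasts, of splits that keep groups whole and, for the cocktails, without the 3 lowest GC deciles and with each line as 1 sample were chosen only after the result was seen. For the last 2 the bounds were written before their values were seen. A difference between groups marked the interaction of donor and cocktail, with 2132 genes called by limma (1030 positive, 1102 negative). The interaction of strain and B was marked for the same reason, with 5229 genes (2565 positive, 2664 negative).

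Many genes stood at 0 in 1 library and above 100 in its replicate, 676 in all, and 654 of them (96.7%) lay in the 3 lowest of 10 GC deciles. Examples, chosen after their values had been seen, were Olfr920, an olfactory receptor gene, Mup6, a major urinary protein gene, and Vmn1r202, a vomeronasal receptor gene. If the authors had normalised within strata of GC content, values between 1 and 100 should be less than 0.5 times as common in the lowest decile as in the 5 highest. They made up 18.81% there against 30.21%, a shortfall that leaves this cause open and could follow from other steps. Reads shared within large gene families may add to it but are unlikely to be the whole cause, since 31.1% of the genes belonged to the listed families, against 13.8% of all low-GC genes and 6.4% of all genes.

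Cocktail effects rested on 1 line per cocktail in each donor or strain. For adding B to KF, the log2 fold changes in ICR and Sox2-GFP lines had a correlation of -0.053 across 16275 genes, which are not independent replicates. Of 1164 genes called in both, 384 (33%) changed in the same direction and 780 in opposite ones. Differences between lines that do not follow the cocktail would give a low correlation. So would an effect of B that differs between strains, and the values cannot tell these apart. For BKF against KMF the correlation between embryonic and tail-tip lines was 0.01, with 208 of 451 genes (46.1%) in the same direction. With each line as 1 sample, 2.76% and 3.29% of genes had an unadjusted p below 0.05, which cannot tell. The bound of 5% set beforehand to exclude an effect was wrong for 2 lines against 2, since 37 and 38 genes still passed adjustment and an effect on few genes is not excluded. Without the 3 lowest GC deciles the share called rose to 30.67% from 25.67% for adding B to KF. For BKF against KMF it rose to 13.17% from 10.86%. Genes of these deciles made up 30.88% of tested genes but 20.23% and 19.13% of called genes, so a rise followed. Normalisation within GC strata would act on every decile, so this test cannot exclude it.

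Other splits of the same libraries into groups of the same sizes were counted, but 99 of 100 for miNSC against fibroblasts and 32 of 35 for each other comparison parted the replicates of a group. For miNSC against fibroblasts, 1 of 100 splits, the real one, reached the real count (12450 genes, highest other 10463). With each group kept whole it was again 1 of 100 drawn splits (highest other 11054). Every other split mixed miNSC and fibroblast groups, so this rank shows only that these cell types differ. It does not show that each call is free of chance. For the 6 other comparisons, groups kept whole gave 3 splits, too few for a share under 0.05. Among all 35 splits, 1 reached the real count for the embryonic against tail-tip donor (5377 genes, highest other 3846) and 1 for ICR against Sox2-GFP (6242, highest other 5229). It was 9 for adding B to KF (4177, highest other 6242), 12 for BKF against KMF (1767, highest other 5377), 9 for the interaction of donor and cocktail (2132, highest other 5377) and 2 for that of strain and B (5229, highest other 6242). The highest others of 6242 and 5377 were the strain and donor contrasts themselves, and 5229 was the interaction of strain and B.

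For Hox genes of paralog groups 5 to 9 the mean log2 value over 14 genes was 5.01 ± 1.17 (SD) in 3 tail-tip lines and 3.16 ± 0.73 in 6 others, with an exact two-sided permutation p = 0.0238 over 84 splits, where the smallest possible is 0.0119. This test largely restated the donor contrast on the same libraries, so whether the donor site left this mark stays open. Groups 10 to 13 fell in tail-tip lines against their fibroblasts (0 higher, 6 lower), groups 5 to 9 were mostly higher in skin than in tail-tip fibroblasts (9 higher, 1 lower), and the Sox2-GFP embryonic KF line (4.43) exceeded the tail-tip KMF line (3.73). Fibroblasts left in the cultures are an unlikely source, since the median fibroblast gene stood at 0.21 to 1.23% of its tail-tip fibroblast level in the 4 groups (mean of the medians 0.87%), against 118.55 to 570.37% for the Hox genes. In the 3 lowest GC deciles, or at 0 and above 100 within a group, lay 0 of 15 listed genes. Normalisation by GC content would act on the other deciles too, so this cannot exclude it.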

How the results depend on the processing

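For counts of called genes, a robust variance prior, omissions of genes, leaving out whole groups or lines, and leaving out the NSC libraries with no replicate block were chosen after seeing the data, and the other settings before. The means of groups were chosen before for miNSC against fibroblasts and after for the 4 other comparisons. For the profile position only the pseudocount of 10 and the 2000 most variable genes were chosen before, and for lists only the estimated correlation. No count of called genes moved by over 1.5 times under a pseudocount of 10, no filter, a filter of 50, rescaling by the median of ratios, quantile normalisation, no variance trend or a robust variance prior. The same held without X and Y genes, genes of low GC content or genes at 0 in 1 library and above 100 in its replicate. Quantile normalisation could change little, since all libraries already held 1317 distinct values, the same highest value and a median of 236 or 237. The share of genes called higher moved by less than 10 percentage points under every scaling, most for BKF against KMF, from 48.9 to 39.4% under the median of ratios. Counts with a tool for read counts were not run, because the values are not counts. Depth is unknown, so what depth limits could not be measured. All 186 results for named genes were picked from these same data and were past the threshold in the main fit. Keeping their direction was therefore nearly fixed in advance and says little about other called genes. Under 4585 alternatives all kept it but 1. The exception was Ddx3y in miNSC against fibroblasts, which turned to a log2 fold change of -0.856 with 1.0-year fibroblasts only (adjusted p = 1.68e-10), since only the 2.5-year fibroblasts had it at 0. When any 1 library was left out 2 gene results lost the call, Dach1 and Pcna. With only the groups compared in the fit, 11 of 186 gene results lost it, and the cause was not tested.

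With a fold change of at least 2 asked for beside the threshold, limma called 6468 genes for miNSC against fibroblasts, 6283 for the tail-tip lines together, and 6218, 6513 and 6071 for BKF, KMF and 4F. It called 2158 against NSC, 6371 for NSC against fibroblasts, 1248 for the embryonic against tail-tip donor and 1097 for its interaction with the cocktail. Adding B to KF gave 957, adding M to KF 2765, BKF against KMF 417, adding M to BKF 1470 and adding B to KMF 2287. For strain the count was 1648, for its interaction with B 3005, for passage 2154, for ear against tail-tip 1681, for age 525 and for skin 1856. These counts are lower by construction.

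Replicate numbers did not pair the libraries. Over 78 pairs of 13 groups, deviations of same-numbered libraries had correlations from -0.055 to 0.071 (median -0.002), 0 of them over 0.1. With the replicate block and without the NSC libraries, whose replicates are passages, the count was 3531 for the interaction of donor and cocktail (2132 before), 2992 for BKF against KMF (1767) and 2978 for age (1797). Leaving out the NSC libraries with no replicate block gave 3519, 3012 and 2964, so the rise came from leaving them out and not from the block. No other count moved by over 1.5 times with either, and 135 list results passed with the block, 137 without it and 141 with the NSC libraries.

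With only the groups compared in the fit, adding M to BKF fell from 4240 to 561 genes. Passage 18 against passage 8 fell from 5716 to 2169. Other fits of 2 libraries against 2 moved less and both ways, as adding M to KF (6358 to 7576) and ear against tail-tip (4419 to 3648). Fewer libraries alone do not account for these 2 falls. Replicates differed by a median of 0.207 in tail-tip BKF, 0.15 in 4F passage 8 and 0.158 in 4F passage 18. Other fibroblast and miNSC groups had 0.075 to 0.149. The variance shared over all groups may thus be too small for these lines. With the mean of each line as 1 sample, limma called 62 genes for donor (5377 before), 37 for adding B to KF (4177), 38 for BKF against KMF (1767) and 69 for strain (6242), a test of 2 lines against 2. With group means in these comparisons and miNSC against fibroblasts, 39 of 72 gene results lost the call. Leaving out 1 library, with the lone library assumed to vary like the other groups, gave 1355 to 2802 genes for the interaction of donor and cocktail and 1143 to 2202 for BKF against KMF. It gave 852 to 1257 for age, 2726 to 3885 for adding M to BKF (4240 before) and 2824 to 3492 for ear against tail-tip (4419 before). The cause was not tested.

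The mean profile position of miNSC, 0.854, was 0.865 with a filter of 50, 0.871 without genes at 0 in 1 library and above 100 in its replicate, 0.873 without genes of low GC content and 0.894 over the 2000 most variable genes. It ranged from 0.775 to 0.856 with 1 library left out. List results past the threshold numbered 171 with the preset correlation and 72 with an estimated correlation, and from 147 to 175 under the other settings applied to all libraries. With 1 library left out they ranged from 160 to 184.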

Other observations

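No test was run in this part, and its genes were chosen after their values had been seen. Mki67, a marker of cycling cells, averaged 1728 ± 50.2 in the Sox2-GFP embryonic KF line and 3259.5 to 10420 in the other miNSC groups. The immediate early genes Fosb (24587 ± 0) and Nr4a1 (28060 ± 0) stood highest of all groups there, against at most 7476 and 3351 in other miNSC groups. Egr2, an immediate early zinc finger gene, averaged 3662 ± 223 against at most 899 elsewhere. Gfap, the astrocyte filament gene, averaged 8316 ± 142, near the 10614 ± 390.3 of NSC.

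Pdk1, a kinase that holds back pyruvate oxidation, averaged 6318 ± 0 in the ear 4F line, 4798 ± 325 in the tail-tip BKF line and 4736 ± 145 in the tail-tip KMF line. In the tail-tip 4F line it averaged 696 ± 711 at passage 8 and 1144 ± 680.2 at passage 18. The glucose transporter gene Slc2a1 averaged 3552 ± 0, 2438 ± 9.19, 2002 ± 11.3, 538 ± 94.0 and 241 ± 120.2 in the same groups. The senescence gene Cdkn2b averaged 1272 ± 13.4 and 851 ± 24.0 in tail-tip fibroblasts at 1.0 and 2.5 years and 140.5 or less in every miNSC and skin group and in NSC.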
